A study of Mus musculus with 6 samples.

How the data were processed

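Poly(A) RNA of whole mouse hearts at embryonic day 13.5 was sequenced in 6 libraries, 3 from Tfam KO embryos and 3 from controls. Per the labels' protocols, each library came from 5 pooled hearts, so the replicates were pools of separate embryos. Frozen hearts were extracted with a column kit and polyadenylated RNA was selected on oligo(dT) beads. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.7 and HTSeq 0.5.3 and the mouse build mm9, with no role or order. The strand setting, the gene annotation and the way FPKM (reads scaled by transcript length and by the library total) was computed were not given in the sources used here. No statistical method of the authors was given in the sources used here.

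Each library had a table of 23284 gene symbols, in the same order in all 6 tables, with a value per gene. The deposited values were log2(FPKM + 1). The file names give the FPKM unit, and the log scale was worked out from the values. When the values were turned back from base 2, between 27.3% and 33.7% of the ratios of low genes to Control replicate 1 fell on a common step, as whole read counts divided by length and library total would. With natural logs or base 10 the commonest step held at most 0.781% of them. The columns for coordinates held placeholder words, so no positions are given. The reference annotation used here (GENCODE vM21 on GRCm38, a later build than mm9) served for transcript lengths, GC content and a sequence match.

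Because FPKM keeps the steps of whole reads, the library totals behind the values were recovered from genes whose transcripts all have the same length in the reference, with 240 genes giving the same total in each library. The totals ran from 12370092 to 18078620 reads. With these totals, all 17876 genes above 0 in at least 1 library gave whole reads in all 6 libraries. The tolerance was 1e-05 of a read for low counts and widened with the read count. Recovered reads are known up to a common whole factor per gene, which is the same in every library. On simulated reads for 500 genes, all 500 were recovered in proportion to the reads they were made from.

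Differences between Tfam KO and Control were tested with limma 3.58.1 (R 4.3.3) on the deposited log2(FPKM + 1) values of the 10807 genes with a mean of at least 1 FPKM over the 6 libraries. A linear model with the group as its only term was fitted, variances were moderated with a trend on expression, tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. This design, the gene lists, the rule for named genes and most of the other settings were set before the data were examined.

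The libraries did not sit on a common scale. The median log2 fold change of all tested genes was 0.28 as deposited and 0.01 after each library was divided by a median-of-ratios size factor (0.828 to 1.33). For this reason gene counts are given both as deposited and with size factors, and the words rose and fell are used of genes past the threshold under both. With the deposited scale the moderated variance was the same trend for all genes (an infinite prior degree of freedom, residual SD 0.277 on the log2 scale), which gives very small adjusted p-values. With size factors the prior had 6.2 degrees of freedom and the residual SD was 0.175.

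The fit was tested on simulated reads for 10806 genes drawn with the real means, library depths and a common dispersion, with 200 genes changed. For the comparison of Tfam KO with Control on the deposited scales, 52% of genes changed by 2-fold and 100% of genes changed by 4-fold were recovered, and 41 unchanged genes were called. With size factors these figures were 94%, 100% and 7, with limma-voom on reads 98%, 100% and 10, and with limma on libraries of a common scale 97%, 100% and 22. The median log2 change found for genes changed by 4-fold was 1.59 on the deposited scales. In the same kind of simulation, on libraries of a common scale, camera called a list of 40 genes raised 2-fold and 0 of 30 random lists of unchanged genes. Simulated genes shared the same dispersion, whereas real variances differed between genes with size factors, and genes of few reads were not among those changed. The recovery figures may therefore be too favourable. Genes were also drawn independently of each other. This simulation therefore does not test how camera behaves with correlated members or with the deposited scales.

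Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, which compares a list with all other tested genes, and adjusted over the 30 lists with at least 3 tested members, a list of sex-linked genes being left out by the design. Camera with an estimated correlation and limma's fry were run beside it. Named genes were Tfam, then the 10 with the largest rise and the 10 with the largest fall among genes past the threshold whose KO and control values did not overlap (predicted and numbered symbols left out), then up to 4 members of each fixed list with the smallest adjusted p. A gene that this rule names is not reported here. In marker lists without a gene past the threshold, the 2 members of highest FPKM were given by value. Genes outside this rule are said to be chosen after their values were seen, and the genes in the plots were chosen the same way.

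The other settings chosen before the data were examined were another pseudocount (0.1), no filter, a filter at 5 FPKM, size factors, rescaling to a common total with and without globin genes, quantile normalization, leaving out each library, the replicate number as a block, robust and weighted variance models, and stricter thresholds. Chosen after seeing the data were limma-voom on the recovered reads, removal of a loess trend on GC content (span 0.5) in each library, and size factors combined with leaving out a library or with the block. GC content was available for 9847 tested genes (91.1%). Sequences were compared with blastn 2.17.0. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9. No pair of libraries in a group was close enough to be the same library sequenced again, since recovered reads differed between replicates by a chi-square of 9.04 to 22.0 per degree of freedom.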

Results

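Tfam encodes mitochondrial transcription factor A, a protein that packages mitochondrial DNA (mtDNA) and is needed to transcribe and copy it. Whole hearts of mouse embryos were profiled by poly(A) RNA sequencing at stage E13.5 in 2 genotypes. In the Tfam KO group both Tfam alleles were floxed, and in the Control group 1 allele was floxed. Both groups carried Cre recombinase in the Nkx2-5 locus, which is active in the cardiac lineage. Each group had 3 libraries and each library was a pool of 5 hearts. The comparison addresses how the heart transcriptome differs when the cardiac lineage carries no intact Tfam allele.

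The libraries of Tfam KO replicates 1, 2 and 3 held 12544836, 13810597 and 16709959 reads, and those of Control replicates 1, 2 and 3 held 13931380, 12370092 and 18078620. Between 15586 and 16063 of the 23284 listed genes were above 0 in a library. A large share of reads fell on Rn45s, the precursor of ribosomal RNA. This share was 25.4%, 31.2% and 14.95% in the KO libraries and 32.5%, 31.6% and 27.8% in the controls. The FPKM values also differed in overall scale. The median deviation of tested genes from their means was 0.18, -0.10 and 0.34 on the log2 scale in the KO libraries and -0.24, -0.17 and 0.00 in the controls. The median gene was 0.28 higher in KO hearts on the log2 scale as deposited and 0.01 higher with size factors, and changes are read against that shift.

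**Figure D1:**
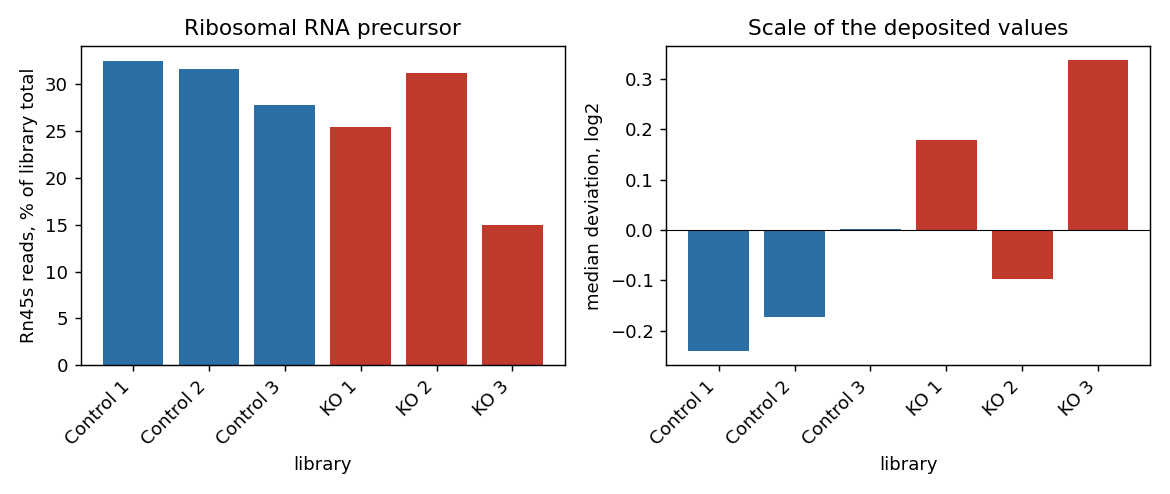
Left, reads on Rn45s as a percent of the library total. Right, median deviation of the 10807 tested genes from their mean over the 6 libraries (log2). Each bar is 1 library, blue for Control and red for Tfam KO (KO). Tfam KO replicate 3 had the lowest Rn45s share (14.95%) and the highest median deviation (0.34).

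Tfam itself was measured at 3.97, 4.77 and 6.22 FPKM in the KO libraries and 4.64, 5.55 and 6.62 FPKM in the controls (4.98 ± 1.14 against 5.60 ± 0.994, SD, n = 3 each). The log2 fold change was -0.15 (SE 0.23, limma adjusted p = 0.651), within the spread of replicates. With size factors it was -0.42 (SE 0.15, adjusted p = 0.152). The controls keep 1 intact allele, cells outside the Cre lineage keep both, and the gene-level value also counts exons outside the floxed part, so this value is a weak check of the labels.

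Predicted and numbered symbols are left out of the rankings that follow. Most of the 10 largest rises in Tfam KO hearts were listed targets of the integrated stress response (ATF4), and Cdsn and Fam129a were not. The troponin genes Tnnt1 and Tnni2, histones and the small non-coding RNA Rmrp were among the largest falls. Of the 10807 genes tested, 671 were higher and 125 lower in KO hearts as deposited, so that 84.3% of calls were higher. With size factors, 224 were higher and 270 lower (45.3% higher). The calls shared by both were 224 higher and 103 lower genes. Without Tfam KO replicate 2, whose overall scale lay among the controls, the deposited values gave 2273 higher and 112 lower genes. Without Tfam KO replicate 1 or 3 or Control replicate 1, 2 or 3 they gave 302, 331, 234, 284 or 396 higher genes and 95, 99, 52, 95 or 55 lower genes.

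With predicted and numbered symbols left out, the 10 largest rises were those of Asns, Nupr1, Trib3, Slc7a3, Mthfd2, Cdsn, Ddit3, Phgdh, Fam129a and Cth. Asns, which makes asparagine, rose from 4.05 ± 0.392 to 86.2 ± 22.0 FPKM (log2 fold change 4.08, SE 0.23, adjusted p = 8.92e-66). With size factors its log2 fold change was 3.78 (adjusted p = 1.15e-06). Mthfd2, a mitochondrial folate enzyme, rose from 7.15 ± 1.28 to 81.6 ± 29.7 FPKM. Trib3, a pseudokinase induced by stress, rose from 1.10 ± 0.453 to 23.9 ± 4.97 FPKM, and the transcription cofactor Nupr1 from 1.57 ± 0.915 to 28.5 ± 1.37 FPKM. Slc7a3, a cationic amino acid transporter, rose from 0.338 ± 0.181 to 14.6 ± 4.05 FPKM. Fam129a rose from 1.25 ± 0.0546 to 12.7 ± 1.88 FPKM. Cdsn, known for its protein in the skin's corneodesmosomes, was at 0.181 ± 0.0520 FPKM in controls and 9.71 ± 0.938 FPKM in KO hearts. In each of these genes all 3 KO libraries lay above all 3 controls.

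The list of 43 targets of the integrated stress response, a program driven by the transcription factor ATF4, was raised almost throughout. Of the 41 members tested, 40 were higher and 0 lower as deposited, and 40 and 0 adjusted over the list alone. With size factors 39 were higher and 0 lower. The list's median log2 fold change was 1.85 as deposited and 1.53 with size factors. It was higher than other genes by camera (adjusted p = 8.52e-173), with an adjusted p = 0.0582 with an estimated correlation (0.0296 with size factors), and fry gave an adjusted p of 0.00828. The members covered serine and one-carbon synthesis (Phgdh, 4.49 ± 1.02 to 34.6 ± 10.8 FPKM), the breakdown of homocysteine (Cth, 0.232 ± 0.0992 to 6.52 ± 1.37 FPKM) and the transcription factor Ddit3 (6.04 ± 0.909 to 47.7 ± 9.86 FPKM). The next 4 were chosen after their values were seen. Atf4 itself rose from 44.2 ± 5.20 to 198 ± 33.5 FPKM, its relative Atf5 from 2.002 ± 0.462 to 15.7 ± 3.20 FPKM, and the secreted factor Gdf15 from 0.352 ± 0.312 to 6.33 ± 1.83 FPKM. Fgf21, another secreted factor, was listed at 0 in all 3 controls and at 0.926, 0.459 and 0.506 FPKM in the KO libraries. It fell under the filter and was not tested.

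**Figure D2:**
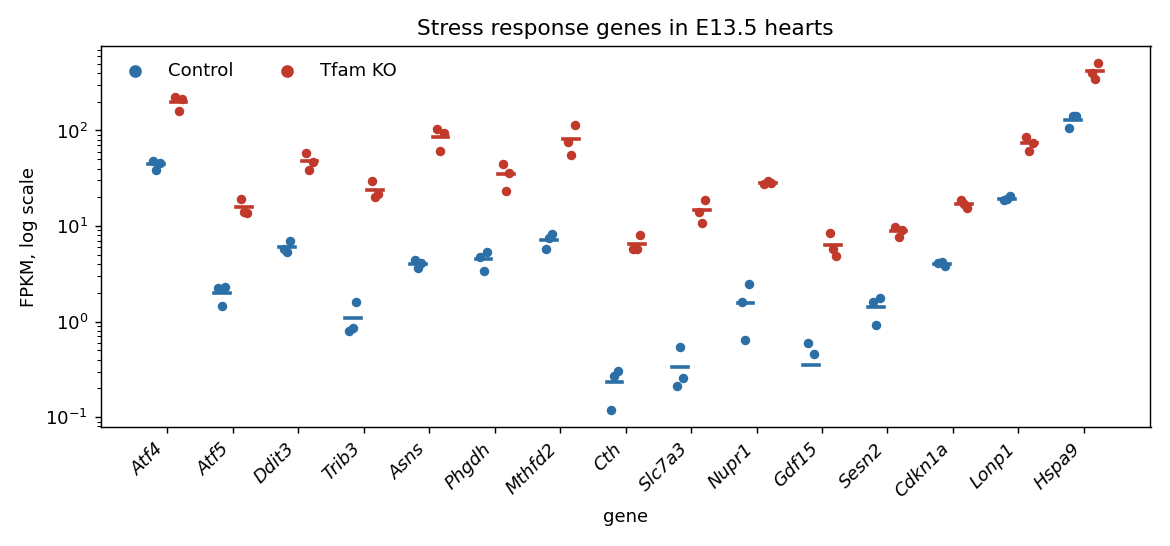
FPKM of stress response genes in each library on a log axis, blue for Control and red for Tfam KO. Points are libraries (n = 3 per group) and bars are means. Every KO point lay above every control point of its gene. The Gdf15 value of Control replicate 2 was 0 and has no point.

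Some chaperones and proteases of the mitochondrial matrix and inner membrane rose. Of 20 tested, 6 were higher and 0 lower as deposited (8 and 0 adjusted over the list alone), and 5 were higher and 0 lower with size factors. Hspa9, the mitochondrial Hsp70, rose from 130 ± 21.1 to 419 ± 79.2 FPKM and the matrix protease Lonp1 from 19.4 ± 0.970 to 73.1 ± 11.9 FPKM. Hspd1 rose from 199.7 ± 39.3 to 409 ± 135 FPKM, and Dnaja3 by 1.09 on the log2 scale. Camera called the list higher (adjusted p = 0.000258), but not with an estimated correlation (adjusted p = 0.995).

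Of 24 genes that keep and transcribe mtDNA, 4 were higher and 0 lower as deposited (8 and 0 adjusted over the list alone), and 1 was higher with size factors. Lrpprc, which stabilises mitochondrial mRNA, rose from 17.8 ± 3.15 to 39.1 ± 8.51 FPKM. Pnpt1, Supv3l1 and Mterfd1 had log2 fold changes of 0.77, 0.75 and 0.73 and passed as deposited only. Camera did not call the list as deposited (adjusted p = 0.13) and called it higher with size factors (adjusted p = 0.0423, but 0.728 with an estimated correlation). Of 17 regulators of mitochondrial biogenesis, Sirt3 and Pprc1 passed as deposited (2 higher, 0 lower, and 2 and 0 adjusted over the list alone) and 0 with size factors (2 higher and 1 lower at an unadjusted p under 0.05, 0 by limma-voom, camera adjusted p = 0.928). None of the 13 subunit genes encoded in mtDNA was listed under the symbols searched, so they were not analysed here.

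Mitochondrial ribosomal protein genes went both ways. Of 76 tested, 11 were higher and 2 lower as deposited (15 and 4 adjusted over the list alone), against 3 higher and 6 lower with size factors. Mrps18a and Mrpl47 rose by 1.06 and 1.01 on the log2 scale. Mrpl34 fell from 18.03 ± 5.35 to 7.21 ± 4.36 FPKM and Mrpl52 from 41.7 ± 5.17 to 19.0 ± 1.37 FPKM. The list was not called (adjusted p = 0.985). Cytosolic ribosomal protein genes had a median log2 fold change of 0.54 as deposited and 0.22 with size factors. Of 78 tested, 19 were higher and 0 lower as deposited (55 and 2 adjusted over the list alone), among them Rps4x, Rps20, Rpl37 and Rpl22l1, with log2 fold changes of 0.79, 0.76, 0.76 and 0.81. With size factors 0 were higher and 2 lower in limma (19 and 3 at an unadjusted p under 0.05, 1 and 2 by limma-voom). Camera called this list higher (adjusted p = 0.000258), but not with an estimated correlation (adjusted p = 0.995). Many ribosomal protein genes have processed pseudogenes, with which their reads may have been shared by the counting.

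Nuclear genes of the respiratory chain showed few changes. None of 36 complex I genes passed in limma as deposited, over the list alone or with size factors, or in limma-voom on reads. At an unadjusted p under 0.05, 8 were higher as deposited and 2 lower with size factors. Their median log2 fold changes were 0.30 and -0.02 on those scales (camera adjusted p = 0.807). Of 27 genes of complexes II to IV, 3 were higher and 0 lower (3 and 0 adjusted over the list alone, camera adjusted p = 0.985). Cox6a2, the muscle form of a cytochrome oxidase subunit, rose from 183 ± 31.3 to 620 ± 99.1 FPKM and was the 1 member past the threshold with size factors. Sdhb and Uqcr10 had log2 fold changes of 0.81 and 0.68 and passed as deposited only. Of 17 ATP synthase genes, Atp5g1 (log2 fold change 0.80) passed as deposited (1 higher, 0 lower, and 1 and 0 adjusted over the list alone, camera adjusted p = 0.725). With size factors 0 were higher and 1 lower.

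Fuel metabolism genes changed in single members. Got1, a cytosolic aminotransferase, rose from 31.0 ± 2.93 to 84.0 ± 12.4 FPKM. It was 1 of 3 higher genes among 24 of the citric acid cycle and pyruvate dehydrogenase (10 higher and 0 lower adjusted over the list alone), with Cs at a log2 fold change of 0.67 as deposited only. Camera called this list higher (adjusted p = 0.0265), but not with an estimated correlation (adjusted p = 0.995), nor without Tfam KO replicate 1, Control replicate 1 or Control replicate 3 (adjusted p = 0.0521, 0.164 and 0.0638). Of 26 fatty acid oxidation genes, 4 were higher and 0 lower as deposited (5 and 0 adjusted over the list alone, camera adjusted p = 0.414). Acot2 rose by 1.25 on the log2 scale, and Lpl, Acsl1 and Echs1 passed as deposited only. Hexokinase 2 (Hk2) rose from 12.3 ± 2.82 to 26.2 ± 3.33 FPKM and was the 1 glycolysis gene of 24 past the threshold under both scales (3 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.985). Of 22 targets of the hypoxia factor HIF, 4 were higher and 0 lower as deposited (4 and 0 adjusted over the list alone, camera adjusted p = 0.928). Vegfa rose from 22.5 ± 3.71 to 49.6 ± 6.81 FPKM, while Ndrg1, Ero1l and Bhlhe40 passed as deposited only. Of 32 antioxidant genes, 5 were higher and 0 lower as deposited (6 and 0 adjusted over the list alone, camera adjusted p = 0.807), among them Hmox1, Mt2, Prdx6 and Gstm1, and 0 were higher and 1 lower with size factors.

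Of 14 cardiac stress genes, 4 rose, the natriuretic peptides among them. Nppb rose from 37.4 ± 5.11 to 163 ± 23.4 FPKM, Nppa from 1102 ± 59.8 to 3325 ± 839 FPKM, and Ankrd1, a muscle ankyrin repeat protein, from 295 ± 35.7 to 762 ± 143 FPKM. Rcan1 rose by 0.80 on the log2 scale. As deposited 6 were higher and 0 lower (6 and 0 adjusted over the list alone). With size factors 4 were higher and 1, Acta1, was lower (log2 fold change -0.64, adjusted p = 0.0144, chosen after its values were seen). Camera called the list higher (adjusted p = 0.000339), but not with an estimated correlation (adjusted p = 0.995). Without Tfam KO replicate 2 its adjusted p was 0.0535.

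The list of 36 sarcomere and calcium handling genes held changes in both directions. Tcap, which caps titin at the Z disc, fell from 30.2 ± 7.35 to 9.21 ± 1.29 FPKM, and the light chain gene Myl3 fell from 1380.3 ± 328 to 793 ± 24.4 FPKM. Myom2, an M-band protein, rose from 1.97 ± 0.360 to 12.7 ± 6.78 FPKM. Ckm passed as deposited only (log2 fold change -0.69). In all, 2 were higher and 3 lower as deposited (2 and 3 adjusted over the list alone), and 1 was higher and 3 lower with size factors. Camera placed the list lower than other genes (adjusted p = 0.00328), but not with an estimated correlation (adjusted p = 0.995) nor without Tfam KO replicate 1 (adjusted p = 0.0686). The list's own median and mean were 0.05 and 0.04 as deposited, below the shift of 0.28 in all genes, and -0.28 and -0.27 with size factors.

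Camera called the list of 30 cardiac transcription factors lower than other genes (adjusted p = 0.000318), but not with an estimated correlation (adjusted p = 0.995), and fry did not call it (adjusted p = 0.871). Irx3 fell from 11.1 ± 0.158 to 6.08 ± 0.485 FPKM and Hand1 from 12.5 ± 2.58 to 7.02 ± 1.41 FPKM, while Bmp10, a trabecular growth factor kept in this list, rose from 11.3 ± 1.48 to 26.4 ± 11.1 FPKM. Of these, 1 was higher and 2 lower as deposited (1 and 2 adjusted over the list alone), and 1 was higher and 6 lower with size factors. Nkx2-5, chosen after its values were seen, was at 26.5 ± 2.50 FPKM in controls and 17.2 ± 3.55 FPKM in KO hearts. It was past the threshold with size factors (adjusted p = 0.0395) and not as deposited (adjusted p = 0.0787). Both groups carry Cre in 1 copy of this locus. The list's median and mean were both -0.02 as deposited, below the shift of 0.28 in all genes, and -0.29 and -0.31 with size factors, where 12 members were lower adjusted over the list alone.

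**Figure D3:**
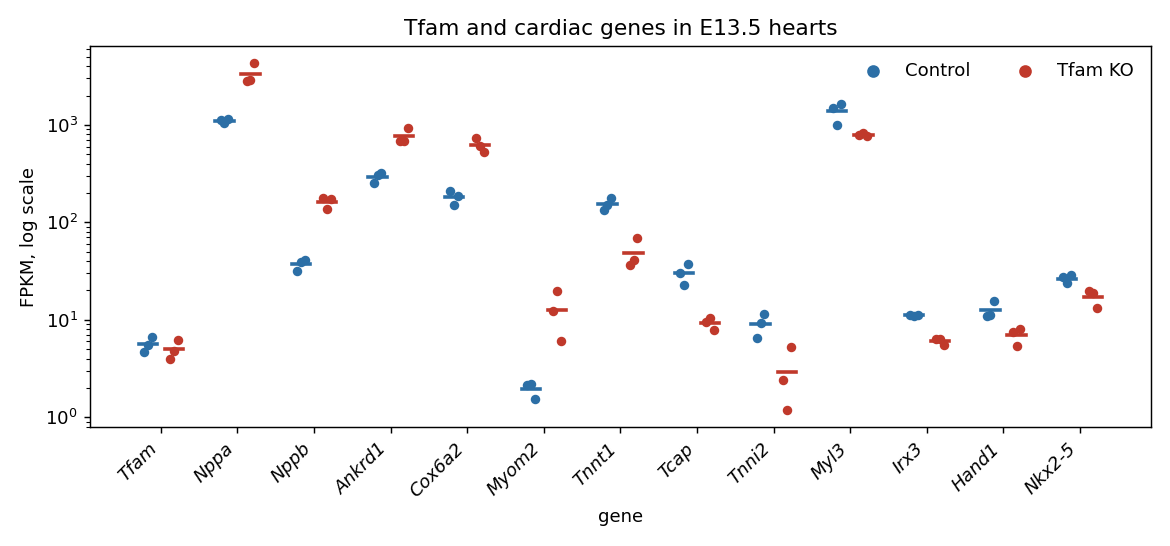
FPKM of Tfam and of cardiac genes in each library on a log axis, blue for Control and red for Tfam KO. Points are libraries (n = 3 per group) and bars are means. Nppb rose from 37.4 to 163 FPKM and Tnnt1 fell from 155 to 48.6 FPKM, whereas the Tfam values of the groups overlapped.

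With predicted and numbered symbols left out, the 10 largest falls were those of Hist1h2ak, Tnnt1, Hist1h4k, Rmrp, Hist1h4b, Tcap, Fam176b, Tnni2, Hist1h2ag and Sox3. Tnnt1, the slow skeletal troponin T, fell from 155 ± 22.5 to 48.6 ± 17.7 FPKM (log2 fold change -1.70, SE 0.23, adjusted p = 1.35e-11, and -2.02 with size factors). Tnni2, the fast skeletal troponin I, fell from 9.05 ± 2.46 to 2.93 ± 2.06 FPKM. The slow skeletal Tnni1, chosen after its values were seen, did not pass (log2 fold change 0.07, adjusted p = 0.828, and -0.26 with size factors, adjusted p = 0.413). Fam176b fell from 8.06 ± 1.49 to 2.26 ± 1.08 FPKM and the transcription factor gene Sox3 from 2.93 ± 0.876 to 0.486 ± 0.208 FPKM. The histone genes Hist1h2ak, Hist1h2ag, Hist1h4k and Hist1h4b fell by 1.71, 1.45, 1.66 and 1.61 on the log2 scale. Their mRNA normally lacks a poly(A) tail and they share near-identical copies, so their values in poly(A) libraries are uncertain. Rmrp, the RNA of the RNase MRP complex, fell too, from 2.87, 3.23 and 5.63 FPKM in the controls to 2.03, 0 and 0.218 FPKM in the KO libraries. For a small RNA such values stand for few reads, and how poly(A) selection affects it was not tested, so its fall is uncertain as well.

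Among cell cycle and p53 genes, single regulators moved. The inhibitor Cdkn1a rose from 4.04 ± 0.218 to 17.1 ± 1.71 FPKM and Gadd45a from 2.25 ± 0.519 to 7.53 ± 1.05 FPKM. They were among 5 higher and 0 lower of 23 p53 targets (7 and 0 adjusted over the list alone, camera adjusted p = 0.205), and 2 were higher with size factors. Ccng1 and Aen passed as deposited only. Cyclin D2 (Ccnd2) rose from 56.7 ± 7.02 to 114 ± 28.8 FPKM and the inhibitor Cdkn1c fell from 215 ± 31.7 to 135 ± 40.01 FPKM. These were the 1 higher and 1 lower gene among 13 CDK inhibitors and D cyclins (1 and 1 adjusted over the list alone, camera adjusted p = 0.592). None of 39 DNA replication genes and none of 55 mitosis genes passed in limma as deposited or over the list alone, and their medians were both 0.18, below the shift of 0.28. At an unadjusted p under 0.05, 2 and 1 of them were higher and 0 lower as deposited, and with size factors 6 and 9 were lower and 1 and 0 higher. With size factors 1 and 2 of them were lower, with limma-voom on reads 2 and 4 were lower, and their size-factor medians were -0.11 and -0.12. Camera did not call these lists as deposited (adjusted p = 0.207 and 0.0893) and called both lower with size factors (adjusted p = 0.0155 and 0.000527, but 0.639 for both with an estimated correlation). None of 23 apoptosis genes passed in limma as deposited, over the list alone or with size factors, or in limma-voom (camera adjusted p = 0.985), and 5 were higher as deposited at an unadjusted p under 0.05. Among 9 interferon response genes tested, 0 passed in limma or limma-voom (1 higher adjusted over the list alone, 2 higher at an unadjusted p under 0.05, camera adjusted p = 0.928). Of 15 immediate early genes, Fos and Fosb rose by 1.35 and 1.19 on the log2 scale, and Egr1 passed as deposited only (3 higher and 0 lower in all, 5 and 1 adjusted over the list alone, camera adjusted p = 0.928). With size factors 2 were higher and 2 lower.

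Markers of the other cells of a fetal heart were examined for a change in makeup. Erythroid markers were lower than other genes by camera (adjusted p = 0.00378), but not with an estimated correlation (adjusted p = 0.995), nor without Control replicate 1 (adjusted p = 0.0504). None of 10 passed in limma on either scale or in limma-voom, and at an unadjusted p under 0.05 none passed as deposited and 2 were lower with size factors. The embryonic globins varied within groups, with Hbb-y at 6233 ± 4587 FPKM in KO hearts and 6710 ± 2113 in controls, and Hba-x at 1406 ± 752 and 1389 ± 473. No other marker list was called. Of 21 fibroblast and valve markers, 4 were higher as deposited (7 adjusted over the list alone), namely Lum, Ogn, Postn and Pdgfra, with log2 fold changes of 0.68 to 0.86, and 0 passed with size factors (4 higher and 2 lower at an unadjusted p under 0.05, 0 by limma-voom, camera adjusted p = 0.251). Of 13 macrophage markers, Cd52, Cx3cr1 and Fcer1g were higher as deposited (5 adjusted over the list alone, camera adjusted p = 0.5), and with size factors 0 were higher and 1 lower. Of 21 endothelial markers, Emcn was higher as deposited (0 adjusted over the list alone, camera adjusted p = 0.13), and 1 was lower with size factors. Of 14 epicardial markers, Krt18 was higher as deposited (2 adjusted over the list alone, camera adjusted p = 0.928). Of 10 smooth muscle and pericyte markers, Pdgfrb was higher as deposited (1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0893), and 2 were lower with size factors. The 4 sex-linked genes tested (3 higher and 0 lower as deposited, 1 and 0 with size factors) were left out of the list tests, and fewer than 3 members were tested in the remaining marker lists. Pf4 and Itga2b of platelets were at 3.01 and 0.992 FPKM in KO hearts and 2.90 and 1.06 FPKM in controls. The liver marker Alb was at 0.569 ± 0.859 FPKM in KO hearts and 2.09 ± 1.09 FPKM in controls (log2 fold change -1.04) and passed as deposited only. Tnnt3 of skeletal muscle was at 2.20 ± 0.319 and 1.26 ± 0.420 FPKM. No neural crest marker reached 1 FPKM.

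**Figure D4:**
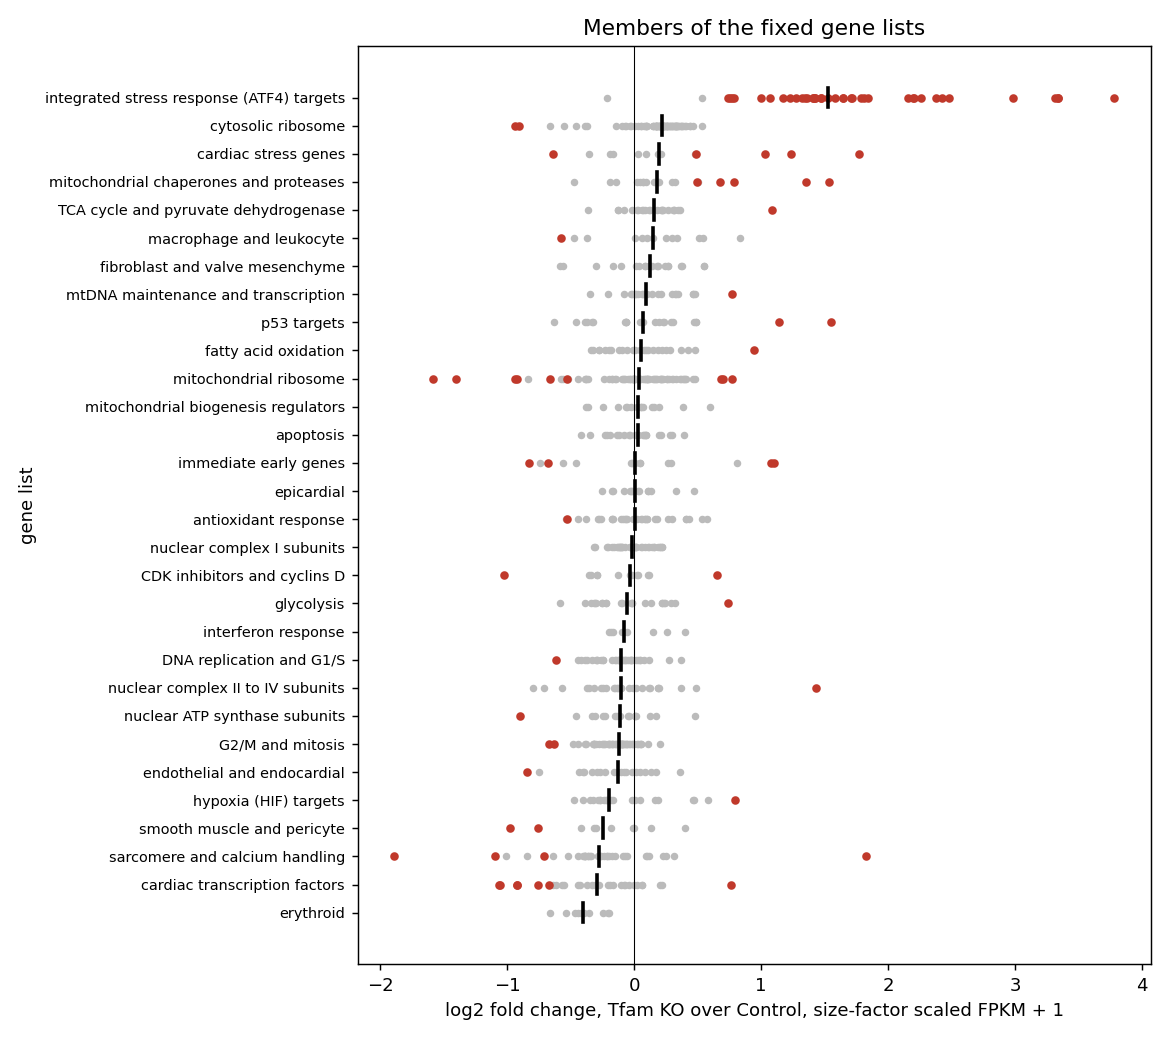
Log2 fold changes (Tfam KO over Control, size-factor scaled FPKM plus the pseudocount of 1) of the tested members of the 30 lists. Each point is a gene, red where its adjusted p was under 0.05 with size factors, and black bars are list medians. The median of the integrated stress response list was 1.53 and those of the other lists lay between -0.40 and 0.22.

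Camera compares a list with all other genes, so lists with a small positive median as deposited could be placed lower. This held for ATP synthase, DNA replication, mitosis, CDK inhibitors and cyclins, glycolysis, hypoxia, interferon, apoptosis, endothelial and smooth muscle genes, of which none was called as deposited, and for sarcomere genes, which were called. The gene-level p-values set a change against the spread among 3 pools per group. As deposited this spread was taken from the trend over all genes, so a gene's own spread did not enter its p-value. With size factors it did in part.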

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

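The voom, GC and combined size-factor settings below were chosen after seeing the data. Of the 93 named genes besides Tfam, the 88 past the threshold as deposited kept their direction in the alternatives run on them. For the rest a change of sign was counted only where the alternative passed the threshold, so their direction may differ between settings. Of the 88 past the threshold as deposited, 31 kept their call in every one, and with size factors 54 of the 93 kept their side of the threshold while 39 lost it. With the filter at 5 FPKM 74 of them had a value and with the GC correction 91. Integrated stress response members called higher numbered 37 to 41 in the settings that tested 41 or more, and 35 of 35 with the filter at 5 FPKM. Their median log2 fold change was 1.53 with size factors and 1.62 with the GC trend removed. Counts of changed genes moved with scaling and with other settings. Against 671 higher and 125 lower genes as deposited, size factors gave 224 and 270, quantile normalization 236 and 283, rescaling to a common total 362 and 197, the same without globin genes 322 and 197, limma-voom on recovered reads 278 and 460, and removal of the GC trend 398 and 331. Their percentages of higher calls were 45.3, 45.5, 64.8, 62.0, 37.7 and 54.6, against 84.3 as deposited. No filter gave 145 and 22, and a minimum of 5 FPKM gave 74 lower genes. Sample quality weights gave 5309 and 311, with a weight of 6.83 for Tfam KO replicate 1 and 0.281 for Tfam KO replicate 2. A log2 fold change of at least 1 left 169 and 35, and an adjusted p under 0.01 left 306 and 67. Leaving out each library gave 234 to 2273 higher and 52 to 112 lower genes, and 138 to 216 and 123 to 341 with size factors (209, 156, 198, 162, 216 and 138 higher and 261, 206, 158, 143, 341 and 123 lower, without Tfam KO replicates 1 to 3 and then Control replicates 1 to 3). The cause of these moves was not tested.

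Lists called higher (5 in the main test) numbered 8 without a filter, 0 with an estimated correlation and 1 with fry. Lists called lower (3 in the main test) numbered 5 without a filter, with size factors, with either rescaling, with quantile normalization and with the GC trend removed, 7 with limma-voom, and 0 with an estimated correlation and with fry. Over the leave-one-out fits 4 to 5 lists were higher and 2 to 5 lower. With an estimated correlation the adjusted p was 0.0582 for the integrated stress response and 0.995 for each of the other called lists as deposited, and 0.0296 for the integrated stress response with size factors. With fry it was 0.128 for cytosolic ribosome, mitochondrial chaperones (0.00796 with size factors) and the citric acid cycle, 0.0681 for cardiac stress, 0.871 for cardiac transcription factors, 0.777 for erythroid markers, and 0.615 for sarcomere genes, whose direction by fry was higher, since fry does not compare a list with other genes. The citric acid cycle list had an adjusted p of 0.0599 with the filter at 5 FPKM and 0.0656 with quality weights, and from 0.00516 to 0.164 over the leave-one-out fits. The cardiac stress list had 0.139 without a filter and 3.55e-06 to 0.0535 over those fits, the sarcomere list 1.64e-07 to 0.0686, and the erythroid list 4.42e-06 to 0.0504. The cause of these changes was not tested.

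Tfam stayed lower in all settings. It passed the threshold with quality weights (log2 fold change -0.36, adjusted p = 0.0351) and with the GC trend removed (-0.49, adjusted p = 0.0413), while its adjusted p ran from 0.0351 to 0.967 over all alternatives. The deposited values left 52% of simulated genes with a 2-fold change called, which limits what small changes can be seen.

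With the replicate number as a block, 2083 genes were higher and 241 lower, and with size factors and the block 287 and 394, with 6 lists lower. The correlations of deviations between libraries of the same number were 0.36, 0.05 and 0.17, so the numbers were not taken to pair the samples, and Tfam KO replicates 2 and 3 correlated more with a control of another number as deposited. In this balanced design the block leaves fold changes as they are.

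The test on read counts with edgeR and DESeq2 that was planned for files holding counts was not run, since the deposited values are log2 FPKM. Limma-voom on the recovered reads took its place.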

Other observations

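The gene groups and genes in this part, and all tests but the splits for stress response members and the sequence match of Gm20594, were chosen after the results were seen. Aminoacyl-tRNA synthetases of the cytosol and of mitochondria were compared. With size factors 14 of 20 cytosolic enzymes were higher and 0 lower in KO hearts (median log2 fold change 0.99), against 0 of 16 mitochondrial enzymes in limma in either direction (2 higher and 1 lower at an unadjusted p under 0.05, 0 by limma-voom, median 0.01). As deposited 14 and 1 were higher. Of the cytosolic list, Sars rose from 16.7 ± 1.60 to 71.3 ± 12.7 FPKM, Gars from 38.0 ± 5.00 to 155 ± 41.4 FPKM and Lars from 11.1 ± 1.72 to 46.3 ± 14.1 FPKM. Gars and Kars, counted as cytosolic, encode the mitochondrial enzymes as well, and the mitochondrial list holds neither. Of these, Gars rose and Kars did not pass with size factors (log2 fold change 0.08, limma adjusted p = 0.809). The lists therefore do not fully separate the compartments. The stress response list holds 9 of the 20, all 9 of them higher with size factors, and of the other 11, 5 were higher. The mean log2 difference between the lists was 2.05 ± 0.117 in KO libraries and 1.10 ± 0.0196 in controls (n = 3 each). This difference of 0.94 had an exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow. The mitochondrial mean includes Lars2, at 1142 ± 267 FPKM in KO libraries and 1381 ± 199 FPKM in controls. Lars2 was far above the other members of that list and had its lowest log2 fold change with size factors (-0.62, limma adjusted p = 0.191). Other genes of amino acid metabolism also rose, Bcat1 from 0.384 ± 0.133 to 6.20 ± 1.91 FPKM and Gpt2 from 1.26 ± 0.334 to 9.07 ± 1.93 FPKM. Slc25a33, a mitochondrial pyrimidine nucleotide carrier, rose from 1.47 ± 0.466 to 9.44 ± 1.53 FPKM, the metalloreductase family gene Steap1 from 0.266 ± 0.0863 to 5.83 ± 1.496 FPKM and Cyb5r1 from 8.62 ± 0.854 to 55.4 ± 10.2 FPKM.

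Sex-linked transcripts were looked at in the pools. The Y-linked genes Ddx3y, Eif2s3y and Kdm5d were at 5.75 ± 1.63, 8.98 ± 0.815 and 2.08 ± 0.442 FPKM in KO pools and 1.95 ± 0.490, 3.94 ± 0.672 and 0.763 ± 0.124 FPKM in control pools. All 3 were higher as deposited and with limma-voom, 1 with size factors (adjusted p = 0.0488 for Ddx3y, 0.0512 for Eif2s3y and 0.0823 for Kdm5d) and 0 with the GC trend removed. Xist was at 13.6 ± 7.44 and 15.2 ± 5.29 FPKM (limma adjusted p = 0.488 as deposited and 0.335 with size factors). Each of these Y-linked genes was higher in all 3 KO pools than in all 3 control pools. More male hearts in the KO pools would give such values, while Xist did not pass on either scale. The sex of the embryos was not examined in another way, so for sex-linked genes sex makeup cannot be told apart from genotype. Reads of the library total that fell on no listed gene made up 21.9%, 23.1% and 21.3% of the KO libraries and 27.4%, 25.9% and 23.7% of the controls (exact two-sided permutation p = 0.1, the smallest possible).

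The first pattern is the excess of higher genes as deposited. With Rn45s reads left out of the library totals the median log2 fold change was 0.18, against 0.28 as deposited, with 523 higher and 183 lower genes. Reads on Rn45s thus made up only part of the measured shift. The median deviations were then 0.09 (SD 0.11) in KO libraries and -0.09 (SD 0.09) in controls. The lowest KO library (-0.03) lay below the highest control (0.01), so whether the rest is a difference between the groups is not decided. With size factors 45.34% of calls were higher, and totals of the listed genes other than Rn45s left a median of 0.0366 (246 higher and 246 lower genes). Both settings centre the tested genes, which hold 99.0% of those reads, so neither decides the source of the shift. A difference in library scale and a true rise of most mRNA cannot be told apart. Such a difference could come from reads on Rn45s, from these and reads on no listed gene, or from another source.

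The second pattern is the fall of replication-dependent histone genes, of which 15 of 28 tested were lower and 0 higher with size factors, with a median log2 fold change of -0.83. Log2 fold changes fell with GC content, to a median of -0.22 in the eighth of genes highest in it, which held 50% of the lower and 7.51% of the higher calls with size factors among genes with a GC value. But with that trend removed the histone median was -0.72 and 11 were lower, which argues against GC content as the whole cause. With size factors the median of 39 replication genes was -0.11 (SD 0.19), a smaller fall than that of the histones. Camera called this list lower (adjusted p = 0.0155), but not with an estimated correlation (adjusted p = 0.639). How far fewer cells in S phase would lower these genes is not known here, so this does not decide the question. Fewer cells in S phase, a weaker carry-over of RNA without poly(A) tails and a Tfam-dependent change in histone mRNA cannot be told apart. The 1 KO library with an Rn45s share inside the control range, replicate 2, had a histone median below every control. This goes against carry-over, but a single library is too few to decide.

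The last pattern is Gm20594, a gene resembling mitochondrial 16S ribosomal RNA (mt-Rnr2), which fell from 95.1 ± 84.3 to 8.13 ± 4.09 FPKM (log2 fold change -3.17 as deposited and -3.47 with size factors). All 3 KO libraries lay below all 3 controls, and Control replicate 3 alone was at 192 FPKM. The reference transcript matched mt-Rnr2 at 88.5% of 435 aligned bases, and 52 of its 400 stretches of 50 bases differed from mt-Rnr2 at no more than 2 positions. The reads may therefore come from the mitochondrial ribosomal RNA, whose synthesis needs Tfam, and this is a hypothesis, as the reads themselves were not analysed here. A change of the nuclear gene stays open.

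Grouping the 6 libraries in other ways makes 10 splits with the real one, too few for a share under 0.05. The real split gave 796 genes as deposited (highest other 25), 494 with size factors (highest other 1) and 40 stress response members (highest other 6), and in each case 1 split, the real one, reached that number. For gene lists the real split gave 8 called lists, and 7 of the 10 splits gave as many, the highest other having 13. The number of lists called by camera at the preset correlation therefore does not set the real grouping apart, and chance cannot be excluded for it.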
